A study of Mus musculus with 2 samples.

How the data were processed

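Acetylation of lysine 9 on histone H3 (H3K9ac), a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation with sequencing (ChIP-seq) in mouse limbs on embryonic day 14.5. There was 1 group with 2 biological replicates of mixed sex, and each replicate was a pool of limbs, from 24 embryos in replicate 1 and 34 embryos in replicate 2, per the labels. Group and replicate numbers were taken from the labels, and the replicates are separate tissue pools. No other tissue, stage or mark was used here, so no test between groups was made.

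The deposited data were 4 peak lists on the mouse assembly mm10. Per the README files deposited with the samples, the lists of replicate 1 and replicate 2 were each derived from that replicate's own filtered alignments and 1 control file, and the pooled list from the alignments of both. The replicated list was derived from the pooled list and the lists of both replicates, per the same files. The aligner, the peak caller, their versions, the thresholds and the rule that kept a peak as replicated are not given in the sources used here. Each peak carries a score, a signal value and the −log10 of a p and a q value, all deposited by the authors. The signal value is called enrichment here, and what the authors scaled it against is not stated in the lists. These values are the authors' own for each peak, and they were used only to describe, rank or filter peaks within a list. The score column was not needed. The lists hold no read counts, so the depth of each sample is unknown and no counting interval is given.

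Protein-coding genes and their transcript starts came from GENCODE release M21 (GRCm38, the assembly that mm10 names), with 21853 genes and 54361 transcript starts on chromosomes 1 to 19, X and Y. Chromosome lengths, gaps and CpG content came from the GRCm38 sequence. No peak reached past a chromosome end, and the peaks within each list did not overlap one another. Peaks outside the assembled chromosomes were left out of all comparisons.

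Peaks of the replicates counted as shared when they overlapped by at least 50% of either peak. The share was set against 100 shuffles of the peaks within their chromosome, outside gaps, which can give no one-sided p below 0.0099. Genomic location was assigned by the peak midpoint, first to a promoter (within 1 kb of a protein-coding transcript start), then to an exon, an intron or the space between genes, against 100 shuffles with a smallest two-sided p of 0.0198. A gene was called marked when a peak overlapped the 1 kb on either side of any of its transcript starts. Its enrichment is the highest value among those peaks, and a peak that reaches the starts of several genes counts for each of them.

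The 20 gene lists, of tissues the limb holds, tissues it lacks and genes most cells use, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The lists cover limb patterning, the 5′ HoxA and HoxD genes, HoxB, HoxC, cartilage, bone, tendon and connective tissue, skeletal muscle, surface ectoderm, endothelium, blood, Schwann cells, central neurons, liver, heart, gut and pancreas, germ line, ribosomal proteins, DNA replication and olfactory receptors. All 348 genes of the lists given by name were found in the annotation. Marked genes of each list were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 20 lists and a threshold of 0.05. For wide domains, replicated peaks at most 1 kb apart were joined. Genes with a start in the widest 5% of promoter domains were compared with the other marked genes by the same test, over lists with at least 5 marked genes. Distal peaks, over 2.5 kb from every protein-coding start, were given to the gene with the nearest start. Their mean number per list gene was compared with 10000 random gene sets of the same size, matched on the length of the gene's nearest-start territory in 10 quantile bins, by a two-sided permutation p that can go no lower than 0.0002. A matched background on promoter CpG content (1000 bp around the start, 10 quantile bins) was among the alternatives. Random sets for promoters and distal peaks were drawn from all protein-coding genes, members of the list included. All these tests count genes or peaks, which are not independent replicates. They describe these libraries, and only 2 replicates stand behind them.

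The rule for named genes took, from each list, the 3 marked members with the highest enrichment and the first 2 unmarked members. Over all genes it took the 10 with the highest enrichment, the 10 in the widest domains and the 10 with the most distal peaks. It also took the 5 distal peaks with the highest enrichment, the 5 list genes marked in 1 replicate only with the highest enrichment there, and the HoxA and HoxD list members. Genes named outside the rule are said to be so where they appear.

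The alternatives changed 1 choice at a time, except the tendon and connective tissue list without Tcf4 matched on CpG, which changed the list and the background. They covered an overlap of 1 bp or of 50% of both peaks, a q value of at most 0.01, the top 50% of peaks by enrichment, lists of equal length, autosomes only, the pooled list, each replicate's list alone, and promoter windows of 500 bp and 2.5 kb. They also covered the 5′ end of each gene only, joining distances of 0 bp and 3 kb, the widest 10%, distal distances over 10 kb, distal peaks joined within 1 kb, and backgrounds matched on CpG or without olfactory and vomeronasal receptor genes. The 5 alternatives added after seeing the data were 200 territory bins, wide domains matched on CpG, each wide domain counted once, and the tendon and connective tissue list without Tcf4, alone and with matching on CpG. Tcf4 was listed in error, since this symbol is an E-protein gene and the connective tissue factor known by that alias is Tcf7l2, which the list also holds.

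The tests were tried on simulated data. Of a planted share of 69.9% of 51141 peaks, 68.6% was recovered. Over 21853 genes, the promoter test called 89.0% of lists of 20 genes with a planted change and 3.50% of unchanged lists, and the wide-domain test 78.5% and 1.00%. The distal test with 10 bins called 33.0% of unchanged lists drawn by territory length, against 2.00% with 200 bins, so the 200-bin value is printed beside each distal call. Matching on CpG content was neither simulated nor repeated with finer bins. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.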

Results

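H3K9ac was mapped in whole limbs of mouse embryos on embryonic day 14.5, a stage at which the cartilage skeleton, muscles and tendons are forming. The group held 2 replicates, pools of limbs from 24 and 34 embryos. Replicate 1 had 51148 peaks and replicate 2 had 85890, which is 68519 ± 24566 peaks (SD, n = 2). The authors' pooled list held 75864 peaks and their replicated list 29450. Of the replicated peaks, 29446 lay on assembled chromosomes, covering 31.4 Mb or 1.15% of the genome, with a median width of 808 bp and a middle range of 460 to 1434 bp. The depth of each library is unknown, since the lists hold no read counts. The labels give no second tissue or stage, so each comparison below is between replicates, between places in the genome or between groups of genes.

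The strongest acetylated regions of the limb were the same in both replicates, and the difference between the replicates lay among weak peaks. In replicate 1, every peak of the top decile by enrichment was shared with replicate 2, and the next deciles were shared at 99.98% and 98.5%. In replicate 2, the top decile was again shared in full, while the next deciles fell to 94.2%, 45.4% and 20.1%. Over all peaks, 27364 of 51141 in replicate 1 (53.5%) and 26886 of 85882 in replicate 2 (31.3%) were shared. Shuffled peaks gave 2.68% ± 0.0678 and 1.65% ± 0.0405 (SD over 100 shuffles, one-sided permutation p = 0.0099 for both, the smallest the shuffles can give). The authors' enrichment values had a Spearman correlation of 0.787 across the 27364 shared regions, which are not independent.

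**Figure D1:**
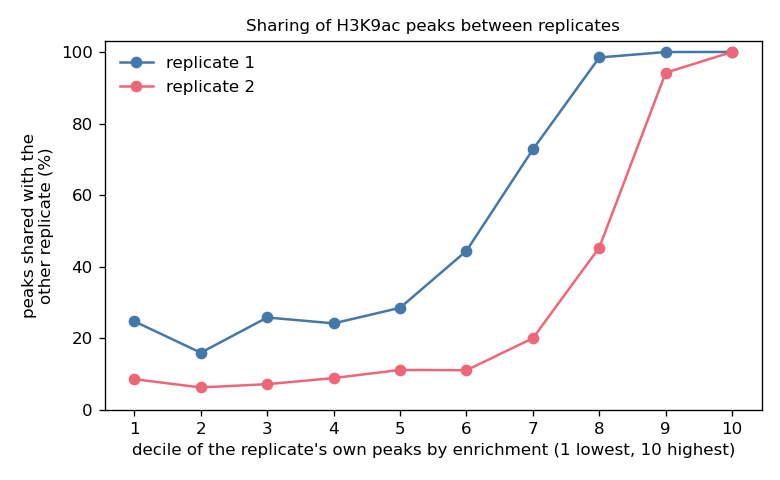
Percent of each replicate's H3K9ac peaks shared with the other replicate (vertical axis), by decile of the replicate's own peaks from lowest to highest enrichment (horizontal axis). Replicate 1 (blue) reaches 98.5% at the eighth decile, where replicate 2 (red), with more peaks in total, stands at 45.4%, and both stand at 100% in the highest.

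Shared regions lay at promoters far more often than regions found in 1 replicate. In replicate 1, 64.4% of shared and 10.3% of unshared peaks were at promoters (odds ratio 15.8), and in replicate 2 the shares were 64.3% and 9.51% (odds ratio 17.2). Fisher's exact p was too small for the software to store in both. Unshared peaks were weaker and narrower, with a median enrichment of 3.28 against 6.43 and a median width of 227 bp against 670 bp in replicate 1, and 3.28 against 7.40 and 214 bp against 745 bp in replicate 2. The list genes with the highest enrichment among those marked in 1 replicate only were all found in replicate 2. They were Hoxb2 (6.19), Hoxc6 (6.13), the muscle actin gene Actc1 (5.46), Hoxb6 (4.90) and Csf1r (4.73), the receptor of macrophage growth factor.

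The replicated list kept the strong and wide part of the pooled list. All 29446 of its chromosomal peaks were pooled peaks, 38.8% of the pooled list, and their median enrichment was 6.42 against 2.90 for the 46410 pooled peaks left out, with median widths of 808 bp and 232 bp. Of the replicated peaks, 91.3% were shared with replicate 1, 95.9% with replicate 2 and 87.5% with both. No left-out pooled peak was shared with both replicates, 9851 were shared with replicate 1 only, 19990 with replicate 2 only and 16569 with neither.

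Acetylation in the limb was concentrated at the starts of protein-coding genes. Of the replicated peaks, 53.5% lay at promoters, 19.8 times the 2.69% of shuffled peaks. Exons held 7.78% of peaks against 4.49% of shuffled ones, introns 23.5% against 42.1%, and the space between genes 15.3% against 50.7%. All 4 differences had the smallest two-sided permutation p, 0.0198, and the exon excess was lost in the top 50% of peaks by enrichment (permutation p = 0.158). The promoter share was lower in the longer lists, at 37.3% in replicate 1, 25.05% in replicate 2 and 25.9% in the pooled list. The deficit in introns was absent from replicate 2 alone (42.3% in both observed and shuffled peaks, permutation p = 0.891) and from the pooled list (42.5% against 42.4%, p = 0.535).

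In total 14007 of 21853 protein-coding genes (64.1%) had a replicated peak at the promoter. The replicates' own lists marked 14161 and 14814 genes, a mean of 66.3% ± 2.11 (SD, n = 2), with 13918 genes in both, 243 in replicate 1 only and 896 in replicate 2 only. Rbm39, a splicing factor gene, had the highest enrichment at 80.1 (peak at chromosome 2, 156178676 to 156180275), followed by the RNA-binding protein gene Sfpq at 76.3 and the nuclear import receptor gene Tnpo1 at 70.97. Tnrc18 (68.8), Ino80d (66.2), B230219D22Rik (65.4), Zc3h4 (64.3), the histone methyltransferase gene Kmt5b (63.9), the homeobox gene Zfhx4 (63.9) and the splicing regulator gene Srsf4 (63.7) completed the 10 highest. Each of these genes was marked in both replicates, with values of at least 51.6 in replicate 1 and 44.9 in replicate 2.

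Limb patterning and cartilage genes carried H3K9ac at their promoters more often than other genes, and genes of tissues outside the limb mostly did not. All 40 limb patterning genes were marked (98.8% ± 1.77 in the replicates' own lists, SD, n = 2), against 64.0% of other genes (adjusted p = 3.26e-07, Fisher's exact test). Prrx1, a homeobox gene of limb mesenchyme, had the highest enrichment of the list at 57.8 (chromosome 1, 163306100 to 163314749), followed by Gli3, the transcriptional effector of hedgehog signalling, at 50.04, and Twist1 at 48.0. Chosen after their values were seen, the forelimb gene Tbx5 had 31.4, the hindlimb genes Tbx4 and Pitx1 had 29.4 and 29.2, and Shh, the signal of the posterior limb margin, had a narrow peak of 4.14 with none in replicate 1. Cartilage genes were marked in 25 of 28 cases (adjusted p = 0.00969, Fisher's exact test), with 91.1% ± 2.53 (SD, n = 2) in the replicates' lists. The parathyroid hormone receptor gene Pth1r, with a peak that also covers a start of Myl3, had 31.9, the cartilage collagen gene Col2a1 had 21.7 and Wwp2 had 21.5. Col10a1, the collagen of hypertrophic cartilage, and Ucma had no peak at the promoter in any of the lists of replicates or replicated peaks. The 10 genes at the 5′ ends of HoxA and HoxD were marked as well (adjusted p = 0.0291, Fisher's exact test), as were all 28 ribosomal protein genes (adjusted p = 3.04e-05) and all 20 DNA replication genes (adjusted p = 0.000592). Rps19 (63.7) led the ribosomal list ahead of Rps6 (49.3) and Rpl32 (47.6), and Cdt1 (31.4), Rrm1 (28.8) and Ccne2 (28.5) led the replication list. The call of the 5′ HoxA and HoxD genes was lost with the pooled list (adjusted exact p = 0.0665), with replicate 2 alone (0.0665) and without receptor genes in the background (0.0639), and that of cartilage with the top 50% of peaks by enrichment (0.474).

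Tendon and connective tissue genes were marked in 17 of 20 cases, which missed the threshold (adjusted p = 0.0944, Fisher's exact test) except with replicate 1 alone (0.0278) and against sets of the same CpG content, given with the other matched sets. Tcf7l2 (45.1), a factor of limb connective tissue, Tcf4 (44.3) and the growth factor receptor gene Pdgfra (44.1) led that list. Tcf4 is an E-protein gene and no marker of connective tissue, and without it 16 of 19 genes were marked (adjusted p = 0.142, Fisher's exact test). Of the members of the list, the tendon membrane protein gene Tnmd and Dpt had no replicated peak at the promoter. Bone genes were marked in 8 of 16 cases. The type I collagen genes Col1a1 (29.4) and Col1a2 (23.6) and the regulator Satb2 (20.1) led, and Ibsp and Bglap, made by mature osteoblasts, were unmarked. Of the skeletal muscle genes 14 of 26 were marked, led by the early regulators Six1 (27.2), Six4 (22.2) and Eya1 (17.8), while Pax3 and Myf6 had no replicated peak at theirs. The muscle share was 42.3% in replicate 1, where it was lower than in other genes (adjusted p = 0.032, Fisher's exact test), and 73.1% in replicate 2, and muscle genes were also lower with the top 50% of peaks by enrichment (adjusted p = 0.000426). Surface ectoderm (13 of 20, led by Krt10 at 14.0, Perp at 10.1 and Dsp at 9.34), endothelium (13 of 16, led by Fli1 at 31.6, Erg at 17.3 and Egfl7 at 12.4) and Schwann cells (6 of 10, led by Mpz at 24.7, a peak that also covers a start of Sdhc, then Mbp at 9.09 and Erbb3 at 8.31) did not pass this test with the replicated list either. Surface ectoderm genes passed as lower with the top 50% of peaks by enrichment (adjusted p = 0.00888, Fisher's exact test). The epidermal genes Trp63 and Krt14, the endothelial genes Tie1 and Emcn, and Plp1 and Foxd3 of Schwann cells had no replicated peak at the promoter.

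Blood genes were marked in 3 of 18 cases (adjusted p = 0.000202, Fisher's exact test). Those were the erythroid genes Klf1 (16.1) and Gypa (6.92) and the macrophage gene Csf1r (4.14), and the embryonic globin genes Hbb-y and Hba-x were unmarked. Central neuron genes were marked in 5 of 20 cases (adjusted p = 0.00125, Fisher's exact test), led by Elavl4 (21.3), Lhx6 (6.83) and Eomes (5.59), and Neurod1 and Neurod2 had no peak at the promoter. The neuron share was 25% in replicate 1 and 50% in replicate 2, and the call was lost with replicate 2 alone (adjusted exact p = 0.149) and with the pooled list (0.314). Liver genes were marked in 3 of 16 cases (adjusted p = 0.000683, Fisher's exact test), but the peaks of Apoh (18.2) and Trf (3.24) also cover starts of Prkca and Gm20425, and Apoa1 (9.62) had no promoter peak in replicate 1 and one of 2.91 in replicate 2. Alb and Afp, the main serum proteins of fetal liver, were unmarked. Heart genes were marked in 3 of 12 cases (adjusted p = 0.0211, Fisher's exact test). Myl3 (31.9) shares its peak with Pth1r, Hand1 (3.15, in neither replicate's own list) and Gata4 (3.07) had weak peaks, and Nkx2-5 and Myl7 had no replicated peak at the promoter. The heart call was lost with replicate 2 alone (50% marked, adjusted exact p = 0.274), the pooled list (0.313) and a promoter window of 2.5 kb (0.483). Gut and pancreas genes (2 of 15, Lgr5 at 6.44 and Cdx1 at 4.34, with Cdx2 and Pdx1 unmarked, adjusted p = 0.000255) and germ line genes (1 of 14, Dazl at 9.38, with Ddx4 and Sycp3 unmarked, adjusted p = 7.64e-05) were also marked less often by the same exact test. The gut and pancreas share was 20% in replicate 1 and 33.3% in replicate 2 and the pooled list. The germ line share was 14.3%, 7.14% and 35.7% in the same lists. Of 1134 olfactory receptor genes, 1 was marked (0.0882%), Olfr94 at 7.03, and Olfr299 and Olfr109 were among those without a peak.

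Several of these comparisons depended on the CpG content of promoters. Random gene sets with the same CpG content were marked at 93.1% for limb patterning, 96.5% for 5′ HoxA and HoxD, 96.1% for ribosomal protein and 92.9% for DNA replication genes. These 4 lists were themselves at 100%, the highest possible share, so the permutation test against matched sets could not have called them higher and decides nothing for them. Cartilage genes stayed higher (89.3% against 68.4%, adjusted p = 0.002, permutation), and tendon and connective tissue genes passed the test (85% against 57.1%, adjusted p = 0.0008, and 84.2% against 54.9% without Tcf4, with the same p). Central neuron genes stayed lower, at 25% against 82.1%, as did gut and pancreas (13.3% against 47.6%) and germ line genes (7.14% against 68.1%), each with an adjusted permutation p of 0.0008. Olfactory receptor genes (0.0882% against 3.50%, adjusted permutation p = 0.0008) also stayed lower. Blood (16.7% against 12.7%), liver (18.8% against 30.5%) and heart genes (25% against 51.6%) did not pass this test (adjusted permutation p = 0.946, 0.560 and 0.119), with a difference of -26.6 percentage points left in the 12 heart genes. HoxB genes were lower than theirs (50% against 84.2%, adjusted permutation p = 0.0166). Their share was 40% in replicate 1, 70.0% in replicate 2 and 80% in the pooled list, which were not set against matched sets.

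**Figure D2:**
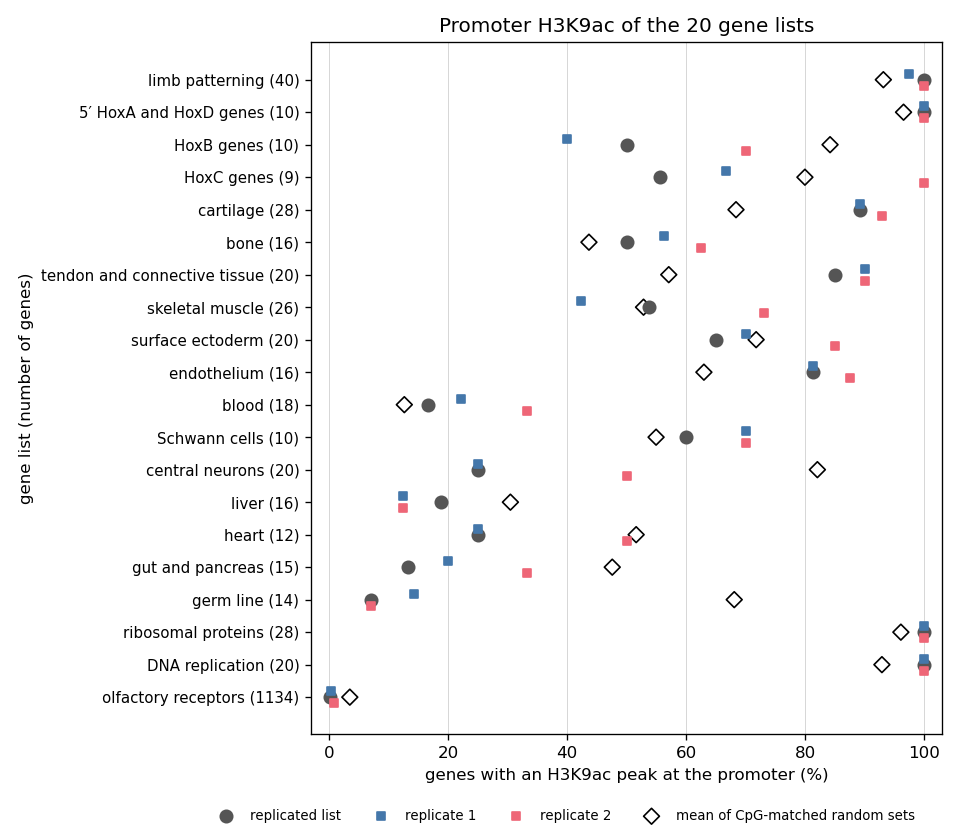
Percent of the genes of each list with an H3K9ac peak at the promoter (horizontal axis), with the number of genes in brackets. Large grey points give the authors' replicated list, blue and red squares the lists of replicates 1 and 2, and open diamonds the mean of 10000 random gene sets with the same promoter CpG content. Cartilage and tendon genes lie above their diamonds, and central neuron and germ line genes lie far below theirs.

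The 5′ parts of the HoxA and HoxD clusters, whose genes pattern the limb from upper arm to digits, lay in the widest acetylated domains found at promoters, while replicated peaks at HoxB promoters reached at most 4.34 and those of replicate 2 at most 6.19. On chromosome 6, 5 peaks joined into a domain of 48712 bp (52219861 to 52268572) over Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13. A single peak of 22244 bp with an enrichment of 53.1 covered the starts of Hoxa7, Hoxa9 and Hoxa10, and Hoxa13 (43.7) and Hoxa11 (39.4) had their own. On chromosome 2, 9 peaks joined into a domain of 46046 bp (74653735 to 74699780) from Evx2 (41.8) over Hoxd13, Hoxd12 and Hoxd11, which share a peak of 42.0, to Hoxd10 (27.4) and Hoxd9 (23.4). Hoxd8 (15.2) lay outside it, in a domain of 2498 bp. HoxB genes were marked in 5 of 10 cases, led by Hoxb2 (4.34), Hoxb9 (4.14) and Hoxb7 (4.02), and Hoxb1 and Hoxb3 were unmarked. The highest replicated peak of the HoxB cluster, 8.07, lay outside the promoter windows (chromosome 11, 96352739 to 96353728). HoxC genes were marked in 5 of 9 cases, led by Hoxc11 (14.3), Hoxc10 (7.99) and Hoxc8 (5.45), and Hoxc4 and Hoxc6 had no replicated peak at the promoter. Neither list passed the promoter test (adjusted p = 0.407 for HoxB and 0.793 for HoxC, Fisher's exact test), but HoxB passed as lower with the top 50% of peaks by enrichment (adjusted p = 0.000487). The replicates marked 40% and 70.0% of HoxB genes, and 66.7% and 100% of HoxC genes.

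**Figure D3:**
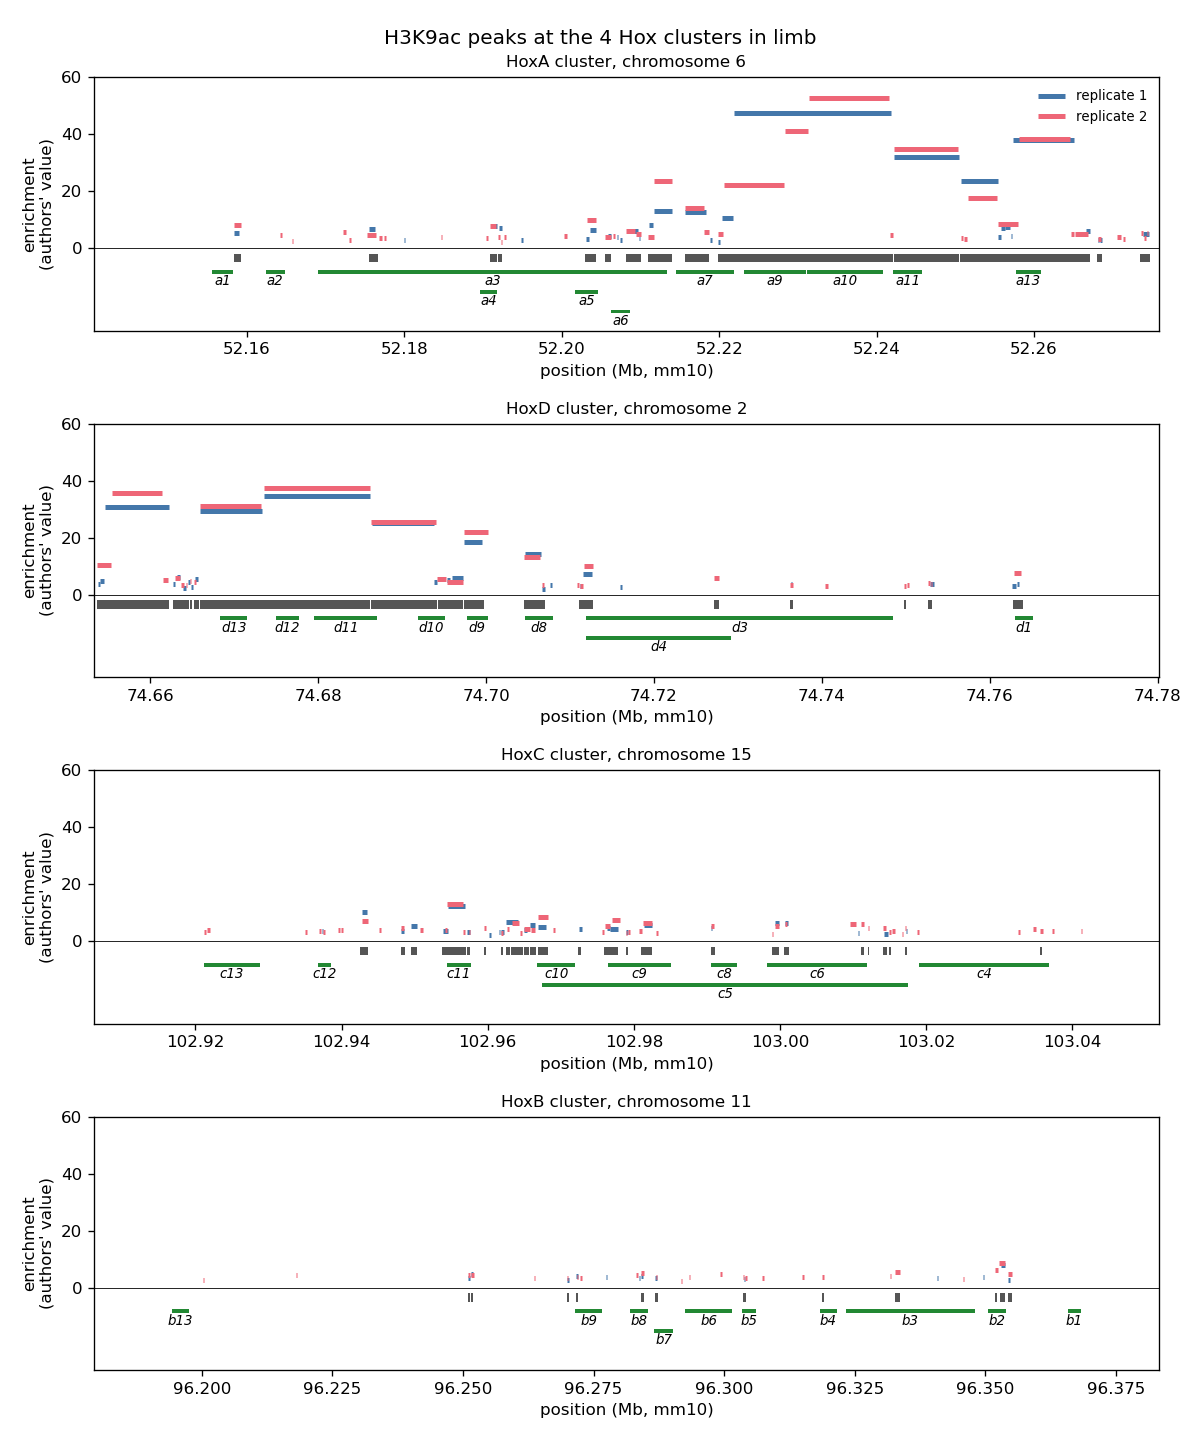
H3K9ac peaks along the 4 Hox clusters (horizontal axes, position in Mb on mm10). Coloured bars give each peak's extent and the authors' enrichment value in replicate 1 (blue) and replicate 2 (red), grey boxes the replicated peaks, and green bars the genes. Peaks reach 53.1 in the replicated list at HoxA and 42.0 at HoxD, and stay at or under 14.3 at the promoters of HoxC and 4.34 at those of HoxB in that list.

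Genes of limb patterning, the 5′ HoxA and HoxD genes, and genes of cartilage, tendon and bone lay in wide domains more often than other marked genes. After joining, 13671 domains overlapped promoters with a median width of 1642 bp, and the widest 5% (684 domains of at least 3937.5 bp) held 819 of the 14007 marked genes, or 5.85%. Of the limb patterning genes, 25 of 40 lay in a wide domain (adjusted p = 2.55e-20, Fisher's exact test). The domains of Prrx1, Twist1 and Gli3 measured 9589, 8442 and 6733 bp. Among 5′ HoxA and HoxD genes it was 9 of 10 (adjusted exact p = 5.08e-10), which rests on 2 domains, and with each domain counted once the adjusted p was 0.0254. Tendon and connective tissue genes lay in wide domains in 10 of 17 cases (adjusted p = 2.76e-08, Fisher's exact test), among them Pdgfra (10354 bp) and Tcf7l2 (7803 bp), and in 9 of 16 without Tcf4 (7695 bp, adjusted exact p = 2.82e-07). Cartilage genes did in 9 of 25 cases (adjusted exact p = 2.34e-05), among them Wwp2 (12636 bp) and Col2a1 (6524 bp). Bone genes did in 3 of 8 cases (adjusted p = 0.025, Fisher's exact test), among them Col1a1 (14216 bp) and Satb2 (4274 bp). The bone call was lost with the top 50% of peaks by enrichment (adjusted exact p = 0.458), the pooled list (0.0522) and the 5′ gene end only (0.658).

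None of the other 9 lists tested passed, but HoxC and ribosomal protein genes did with peaks joined within 3 kb (adjusted p = 0.000323 and 0.0212, Fisher's exact test). HoxC had 1 of 5 genes in a wide domain, skeletal muscle 1 of 14 (Six1, 8151 bp), endothelium 2 of 13 and ribosomal proteins 2 of 28. HoxB (of 5), surface ectoderm (of 13), Schwann cells (of 6), central neurons (of 5) and DNA replication (of 20) had 0. Rps19, with an enrichment of 63.7, lay in a domain of 3554 bp, and Rbm39, with 80.1, in one of 2962 bp. Median enrichment was 33.8 at ribosomal protein genes and 18.1 at limb patterning genes, while median domain width was 2506 bp and 6553 bp.

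**Figure D4:**
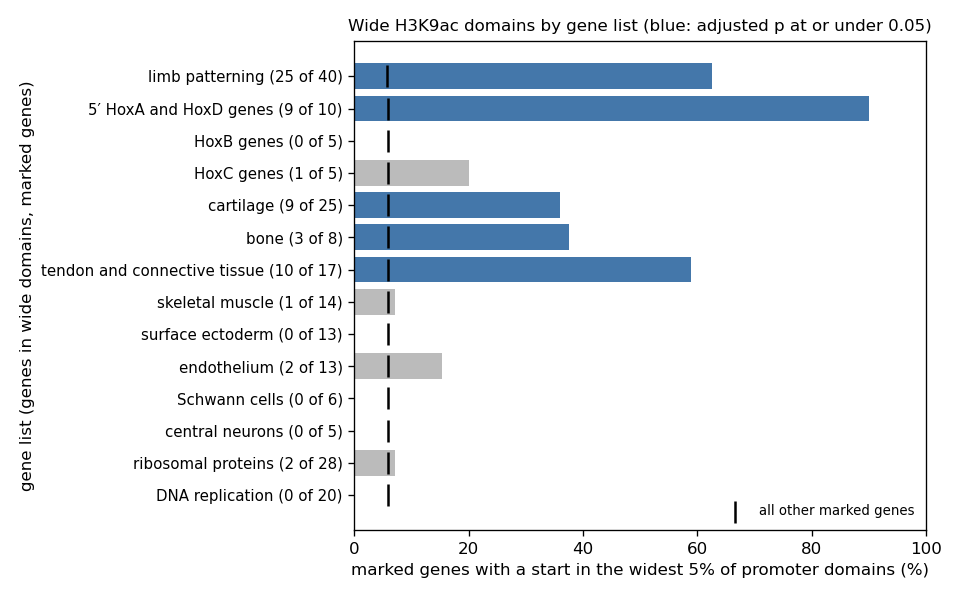
Percent of the marked genes of each list with a start in the widest 5% of promoter domains (horizontal axis), with the number of genes in wide domains and of marked genes in brackets. Blue bars passed the test, grey bars did not, and black ticks give all other marked genes. Limb patterning (62.5%), 5′ HoxA and HoxD (90.0%), tendon (58.8%), cartilage (36.0%) and bone genes (37.5%) stand above the ticks, which lie between 5.68% and 5.86%.

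Limb patterning and cartilage genes were also surrounded by more distal acetylated regions than other genes with territories of the same length. The matched sets held genes with and without a promoter peak, whereas all 40 limb patterning genes had one. No comparison with marked genes only was made for distal regions. Limb patterning genes had 3.63 distal regions per gene against 0.921 in matched sets, 3.94 times as many (adjusted p = 0.002, permutation, and 3.59 times with 200 bins, adjusted p = 0.002). Cartilage genes had 1.93 against 0.606 (adjusted p = 0.00533, permutation, and 0.004 with 200 bins, but 0.573 with the top 50% of peaks by enrichment). As a difference from matched sets, limb patterning had 5.33 regions per gene in replicate 1 and 7.92 in replicate 2, against 2.70 in the replicated list. For cartilage the differences were 2.43 and 6.18 against 1.32. The replicates' own lists hold more peaks, and ratios to matched sets are not given for them, so a stronger relative excess in either replicate is not shown. HoxC genes (1.44 against 0.264, adjusted p = 0.0448, permutation) and tendon genes (2.30 against 0.846, adjusted p = 0.0448) passed with 10 bins, but not with 200 bins (adjusted p = 0.092 and 0.062), and tendon genes not without Tcf4 (0.052). Olfactory receptor genes had fewer, at 0.0176 against 0.257 (adjusted p = 0.002, permutation, and the same with 200 bins). Their difference of -0.240 regions per gene was -0.549 in replicate 1, -1.12 in replicate 2 and -0.0388 in the top 50% of peaks by enrichment. None of the other 15 lists passed, with adjusted permutation p between 0.07 for bone and 1, but bone did with the 5′ gene end only (0.0273) and 5′ HoxA and HoxD with replicate 1 alone (0.00267). Bone genes had 1.81 regions per gene against 0.609, of which 13 lay near Col1a1.

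In all, 10944 replicated peaks (37.2%) were distal, weaker and narrower than the rest, with a median enrichment of 4.02 against 11.96 and a median width of 494 bp against 1165 bp. Of these, 11.7% lay at starts of genes annotated as noncoding. The 10 genes with the most distal regions were Gse1 (27 regions), the homeobox gene Zfhx3 (23), Sept9 (21), Zmiz1 (19), the inhibitor of TGF-beta signalling Smad7 (19), the retinoid receptor gene Rxra (18), Ubash3b (17), Cstad (17), Zfp36l1 (16) and the corepressor gene Ncor2 (16). The distal peak with the highest enrichment, 84.8, lay on chromosome 7 from 73555903 to 73560025, 16218 bp from the nearest protein-coding start, of Chd2, and at the start of the noncoding gene 1810026B05Rik. The next, 65.4, lay on chromosome 10 from 122983121 to 122987192 at the microRNA gene Mirlet7i, with Ppm1h as its nearest protein-coding gene. Those nearest to A830005F24Rik (52.8) and Ndufs3 (52.3) lay at starts of Gm37238 and of Ptpmt1, which the annotation does not class as protein-coding. The one nearest to Ppara (49.2, chromosome 15, 85669730 to 85674585) lay in an intron and at no annotated noncoding start.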

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

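In the replicated list, 4 peaks lay outside the assembled chromosomes, on 3 other scaffolds of the assembly, with enrichment values from 2.15 to 22.8. They were flagged because they lie in sequence that no comparison used. No expected count for these scaffolds was measured, so their number is not shown to be unusual. Replicates 1 and 2 had 7 and 8 such peaks.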

How the results depend on the processing

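The tests with 200 territory bins, with wide domains matched on CpG, with each domain counted once and without Tcf4 in the tendon list were chosen only after the results were seen. Of 666 values recomputed under the alternatives, 610 kept their side of the threshold, and their direction where either value passed, or stayed within 1.5 times for a count. The excess of limb patterning, 5′ HoxA and HoxD, cartilage and tendon genes in wide domains was among these 610 under every alternative run, as was the excess of distal regions at limb patterning genes. A difference that passed in neither setting could change direction and still count among the 610. Bone at promoters did so with matching on CpG, from -14.1 to 6.32 percentage points. The cause of the changes below was not tested, though a background of the same CpG content is meant to remove the part of a difference that CpG content carries. Each value is a difference from the background, in percentage points for location, promoters and wide domains and in regions per gene for distal regions. Depth is unknown, so the number of weak peaks that each library could show is not limited here.

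For location, the exon excess was 0.271 with the top 50% of peaks by enrichment, and the intron deficit turned into an excess of 0.109 with the pooled list and ranged from -7.17 to -0.0148 without each replicate in turn.

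For promoters, matching on CpG left 2 lists higher in place of 5, with limb patterning at 6.86, 5′ HoxA and HoxD at 3.46, ribosomal proteins at 3.91 and DNA replication at 7.10, where lists marked in full could not have passed. It brought tendon to 27.9 (29.3 without Tcf4) and HoxB to -34.2, both past it, turned blood to 4.01, and took liver (-11.7) and heart (-26.6) back under it. With the top 50% of peaks, cartilage (7.83) no longer passed, HoxB (-56.5), skeletal muscle (-37.3) and surface ectoderm (-31.5, turned from an excess) passed as lower. With the pooled list, 5′ HoxA and HoxD (32.2), central neurons (-12.8) and heart (-17.8) no longer passed, nor did 5′ HoxA and HoxD without receptor genes (31.3) or heart with a 2.5 kb window (-15.3). Without each replicate in turn, the ranges were 32.2 to 35.2 for 5′ HoxA and HoxD, 22.2 to 25.2 for tendon, -22.5 to 5.29 for skeletal muscle, -39.8 to -17.8 for central neurons and -39.8 to -17.8 for heart. Replicate 2 alone lost the calls of 5′ HoxA and HoxD, neurons and heart, and replicate 1 alone added those of tendon and muscle.

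For wide domains, joining peaks within 3 kb brought HoxC (73.4) and ribosomal proteins (14.8) past the threshold. Bone no longer passed with the top 50% of peaks (6.96), the pooled list (27.2) or the 5′ gene end only (8.75).

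For distal regions, 2 lists were higher in place of 4 with the top 50% of peaks, the pooled list, a distance over 10 kb, regions joined within 1 kb and 200 territory bins, and between 2 and 3 were without each replicate in turn. HoxC no longer passed with the pooled list (1.79), over 10 kb (0.104), joined regions (0.876), 200 bins (1.17) or either replicate alone (1.08 to 1.69). Tendon no longer passed with the top 50% (0.218), the pooled list (4.45), over 10 kb (0.686), joined regions (0.988), 200 bins (1.38), without Tcf4 (1.33) or either replicate alone (2.41 to 3.33). Cartilage no longer passed with the top 50% (0.114), bone passed with the 5′ gene end only (1.402), and 5′ HoxA and HoxD, at 1.07 to 1.27 without each replicate in turn, passed in replicate 1 alone.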

Other observations

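The gene families and the tests of the Hox clusters and of chromosome X were chosen only after the main results were seen, with the family names fixed before their values. Matching on CpG content was planned, but how it would be read was set after its values were seen. Since T-box, Iroquois, Sox and collagen genes are in part members of the lists already described, each family was also tested without genes of the 20 lists, in the family and in the background. Of 18 gene families taken by symbol, 3 of those tested lay in wide domains more often than other marked genes in both tests. Without list genes, these were histone genes, whose starts lie close together in clusters (17 of 57 marked genes, adjusted p = 7.58e-08, Fisher's exact test), frizzled receptor genes of Wnt signalling (6 of 10, 3.24e-05) and forkhead genes (8 of 31, 0.00094), and with list genes kept the adjusted exact p was 2.26e-07, 3.59e-05 and 0.000999. T-box genes (6 of 10, 3.59e-05), Iroquois genes (4 of 6, 0.000633), Sox genes (6 of 18, 0.00106), collagen genes (8 of 36, 0.00211) and protocadherin genes (4 of 19, 0.0445) passed the exact test only with list genes kept, and 5, 2, 3, 5 and 0 of their genes in wide domains were list genes. Without list genes the counts were 1 of 5 for T-box (adjusted exact p = 0.382), 3 of 12 for Sox (0.0698), 3 of 27 for collagen (0.365) and 4 of 19 for protocadherin genes (0.0629), and the Iroquois genes were too few to test. Zinc finger genes, a large family marked in 341 of 394 cases, lay in wide domains in 16 of 341 (0.509 with list genes kept). No count of each domain once was made for families, so the result for clustered genes such as histones can rest on fewer domains than genes.

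All 78 mitochondrial ribosomal protein genes (adjusted p = 4.77e-15, Fisher's exact test), 37 of 39 proteasome genes (2.88e-05), 57 of 67 histone genes (0.000361) and the zinc finger genes (4.30e-23) were marked more often than other genes. Keratin genes were marked in 7 of 53 cases (7.17e-14), cytochrome P450 genes in 24 of 100 (1.64e-15), protocadherin genes in 19 of 69 (2.87e-09), defensin genes in 0 of 64 (2.58e-28) and vomeronasal receptor genes in 1 of 331 (6.62e-146), all less often. These 9 calls also passed without list genes, while those of Sox (18 of 19, 0.00608), frizzled (10 of 10, 0.0262) and collagen genes (36 of 44, 0.0262) did not (adjusted exact p = 0.121, 0.0658 and 0.297). T-box (10 of 13), forkhead (31 of 44), Iroquois (6 of 6), Wnt (15 of 19), Fgf (18 of 22) and Bmp genes (8 of 11) did not pass for promoters, nor did Wnt (2 of 15), Fgf (2 of 18) and Bmp genes (2 of 8) for wide domains. These family comparisons were not matched on CpG content.

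The domains over the 5′ HoxA and HoxD genes, 9 of 10 of which lay in the widest 5%, could come from joining of peaks up to 1 kb apart or from close spacing of Hox starts. With no peaks joined, single peaks still put 8 of the 10 genes among the widest 5% (at least 2994 bp), which argues against joining as the whole cause. Among these peaks, those at Hoxa13 (11612 bp), Hoxa11 (8263 bp) and Hoxd10 (7826 bp) reached the promoter window of no other protein-coding gene. That argues against close spacing of the protein-coding starts of different genes as the whole cause for these genes. Noncoding starts and several starts of the same gene were not looked at here. Peaks of 22244 and 20277 bp each reached several listed starts, and those of Hoxd9 and Hoxd8 were under 2994 bp. For the clusters as a whole, close spacing and a difference between clusters cannot be told apart. HoxB and HoxC had 10% of their 10 marked genes (1 gene) in such a domain. Their starts lie 10.9 and 13.3 kb apart in the median, against 8.88 and 6.80 kb in HoxA and HoxD. Joining within 3 kb also put HoxC 73.4 percentage points above other marked genes. Promoter peaks were not limited to the 5′ parts, since 8 of the 9 genes Hoxa1 to Hoxa6, Hoxd1, Hoxd3 and Hoxd4 were marked. Their median enrichment was 8.37, against 42.0 in the 5′ genes. The highest value, 20.8, lay at an upstream start of Hoxa3 (52210953 to 52214056), between the Hoxa6 and Hoxa7 genes. That peak is part of the wide domain of Hoxa3 and Hoxa6 (52208128 to 52214056). A replicated peak further inside Hoxa3 had 7.03 (52175573 to 52176665). Of these 9 genes, 2 (Hoxa3 and Hoxa6) lay in a wide domain, so wide domains were not strictly limited to the listed 5′ genes. With 1 such domain in the 3′ parts and 2 over the listed 5′ genes, there are too few to tell whether wide domains are more frequent in the 5′ parts.

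Chromosome X was short of peaks, and most of all of weak ones. It had 1.54 pooled peaks left out of the replicated list per Mb, against 11.6 to 36.8 on the autosomes. Replicated peaks were also fewer on X, at 4.48 per Mb against 7.996 to 21.6. For each replicated peak X had 0.344 left-out peaks, against 1.36 to 1.79. A line over the gene density of the autosomes predicted 13.5 left-out peaks per Mb for X (95% prediction interval 5.68 to 21.4), which argues against gene density as the cause of the few left-out peaks. A line over chromosome GC content predicted 0.501 (-5.91 to 6.91), which includes the observed value, but the GC content of X (39.3%) lies outside the autosomes' 40.5% to 43.8%, so that line was set aside after its value was seen. The GC content of 1 Mb windows, a test added for this reason, gave X 32.4% of the left-out peaks of autosomal windows with the same GC content (95% bootstrap interval 26.9% to 38.2%) and 117% of their replicated peaks (101% to 133%), which argues against GC content as the whole cause. The lower copy number of X in pools that include males may contribute and stays open, with the authors' thresholds, and no biological explanation was tested.

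Genes of blood and of tissues outside the limb might lack promoter peaks because of CpG-poor promoters alone, without regard to tissue. Matching on CpG content moved blood from -47.5 to 4.01 percentage points and liver from -45.4 to -11.7, neither past the threshold afterwards. No deficit beyond that of genes with similar CpG content was shown for these lists. The matched sets may themselves hold genes of other tissues, so CpG content and tissue cannot be told apart for blood and liver. Central neurons (-57.1, from -39.1) and germ line (-60.9, from -56.99) stayed past the threshold after matching. Matching did not shrink these differences, which argues against CpG content as the whole cause for these lists. Gut and pancreas (-34.3, from -50.8) and olfactory receptors (-3.41, from -67.5) also stayed past it, but with smaller differences. Genes in the same bin can still differ in CpG content, and finer bins were not tried. For gut and pancreas and for olfactory receptors, CpG content as the whole cause therefore stays open. The matched sets could include members of the list itself, so the part of the olfactory difference that CpG content carried was not measured. For heart genes (-26.6, adjusted permutation p = 0.119) CpG content and tissue cannot be told apart with 12 genes. No biological explanation was tested.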
